A study of Mus musculus with 6 samples.

How the data were processed

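RNA was measured by single-nucleus sequencing in mice 9 months old, with 1 library in each of 6 groups. The labels describe lysed frozen tissue, nuclei cleaned over sucrose and droplet capture, and name 3′ end sequencing together with 5′ kits. They name hippocampus in titles, the left hemisphere in the protocol and nuclei of brain as tissue. The number of animals per library is not given in the sources used here. The deposited matrices hold whole UMI counts per gene and barcode, made by the authors with Cell Ranger 3.1.0 per the file headers, on mm10 per the submitters' processing notes. Seurat is named in those notes without a version, and its role is not given in the sources used here. Reads were not used here. The matrices list 33457 features, with human APOE added to mouse genes, and 32739 of their identifiers were found in GENCODE vM21. Human MAPT and Cre, on the list of label check genes, were not found among the feature names, nor were Mx2, Cebpd, Pcdhgc3, Lhfpl3 and 9630013A20Rik.

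Comparisons, filters, markers, gene lists, the rule for named genes and the first set of alternatives were fixed from the labels before the data were examined. Cluster names were given after, from markers fixed before. Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs. The mitochondrial limit was passed over by 30.2% of barcodes in FE3, 8.99% in FE4, 21.9% in TAFE3_oil, 26.7% in TAFE3_tam, 20.8% in TAFE4_oil and 11.3% in TAFE4_tam. Doublets were scored in each library with scrublet in scanpy 1.11.5, with exact neighbours and an expected rate of 0.8% per 1000 nuclei. Its own threshold left out 1834 nuclei in FE3, 2181 in FE4, 690 in TAFE3_tam, 940 in TAFE4_oil and 2004 in TAFE4_tam. In TAFE3_oil that threshold marked 0 nuclei, and the top expected share of 9.30% (1082 nuclei) was left out instead.

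Nuclei of all libraries were clustered together on log counts per 10000. The 2000 variable genes were ranked within libraries, without sex-linked, mitochondrial and label check genes. From 30 principal components, 15 exact neighbours per nucleus were linked by shared neighbours and split by Leiden (leidenalg 0.10.2, resolution 1) into 30 clusters. Clusters 6, 13, 17, 20, 22, 28 and 29 were left unnamed, as fixed markers gave no single class. Cluster 17 held oligodendrocyte markers at a doublet score of 0.232, cluster 22 markers of microglia and oligodendrocytes, and cluster 13 haemoglobin genes. No log2 ratio was taken for classes under 50 nuclei in a library, and for T cells only numbers of nuclei are given.

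FE4 was compared with FE3, each TAFE oil library with the FE library of the same APOE allele, and each tamoxifen library with its oil library. TAFE4 was also compared with TAFE3, with oil and with tamoxifen. Groups of 1 library allow no test between animals. TAFE and FE mice differ in P301S tau, Cre and oil together, and tamoxifen comes with the deletion. UMI counts were summed per class and library and divided by the class total, with exact conditional binomial 95% intervals. Counts under 3 were set to 3. Shares of nuclei have exact 95% intervals. Median UMIs per used nucleus were 2366 in FE3, 2255 in FE4, 2428 in TAFE3_oil, 2563 in TAFE3_tam, 2597 in TAFE4_oil and 2140 in TAFE4_tam.

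Members of a list were used with at least 20 UMIs over both libraries and at least 3 CPM in either. The median of their log2 ratios has an interval from 1000 Poisson resamplings and a percentile among 10000 random lists matched on expression. The lists were disease-associated microglia, homeostatic microglia, lysosome and phagocytosis, complement, interferon-response, MHC class I, MHC class II, reactive astrocyte, homeostatic astrocyte, and astrocytic synapse organisation and engulfment. Further lists were cholesterol synthesis, lipoprotein and lipid transport, reactive oligodendrocyte, myelin, presynaptic, postsynaptic, immediate early, heat shock and chaperone, and unfolded protein and integrated stress response. The last were nuclear-encoded oxidative phosphorylation, p53 and DNA damage response, ribosomal protein, mitochondrially encoded, long nuclear RNAs, label check, sex-linked, blood, and neuronal transcripts as a measure of free RNA in glia.

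Named genes had at least 100 UMIs, at least 20 CPM in the higher library and a CPM in the class no lower than in all other nuclei. Mitochondrial and ribosomal protein genes, Y-linked genes, the listed sex-linked genes, Gm and Rik gene models and markers of other classes were left out. Other X-linked genes stayed in. For tau, tamoxifen and APOE4 against APOE3, the 5 highest and 5 lowest were taken by the smaller of the absolute log2 ratios with the same sign in both pairs. For TAFE4_tam against TAFE3_tam and for differences between APOE backgrounds, the 3 highest and 3 lowest were taken. A few genes that met these rules are not reported here. Correlations across genes used genes with at least 100 UMIs.

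Alternatives were resolution 0.5, at least 1000 UMIs, at most 1% mitochondrial UMIs, components centred per library, doublets kept, TMM factors (edgeR 4.0.16, R 4.3.3), means over nuclei, other minima for genes, and genes under the level of other nuclei left out. Added after the data were seen were no mitochondrial filter, the top expected share of doublets left out in every library, neuron classes on their own and 2 more for correlations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used with fixed seeds and a single thread.

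Ratios and list medians were tested on simulated data with 200 changed genes. In astrocytes, planted log2 ratios of -2, -1, 1 and 2 came back with medians of -2.04, -0.98, 0.96 and 2.04, and 95.6% of intervals of unchanged genes held 0. In microglia they came back as -2.07, -0.91, 1.01 and 2.01, and 95.2% of intervals of unchanged genes held 0. A planted list had a median of 1.04 in astrocytes at percentile 100, and an unchanged list lay at percentile 6.01.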

Results

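RNA was counted in single nuclei from brains of mice 9 months old, in 6 groups with 1 library each. FE3 and FE4 carried floxed human APOE3 or APOE4 and were untreated. The 4 TAFE libraries added P301S tau and an astrocyte Cre that tamoxifen switches on, given oil (TAFE3_oil, TAFE4_oil) or tamoxifen (TAFE3_tam, TAFE4_tam). FE3 held 15677 barcodes and 39863569 UMIs, FE4 18171 and 49083723, TAFE3_oil 14885 and 39599801. TAFE3_tam held 14762 and 39050503, TAFE4_oil 16467 and 46995438, TAFE4_tam 16290 and 40581803. Median UMIs per barcode ran from 2090.5 in TAFE4_tam to 2518 in TAFE4_oil. After filters 9114 nuclei of FE3, 14356 of FE4, 10549 of TAFE3_oil, 10127 of TAFE3_tam, 12106 of TAFE4_oil and 12438 of TAFE4_tam were used.

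With 1 library per group there were no replicates, and the intervals in brackets cover counting error alone. Percentiles of gene lists among random lists describe these libraries. Correlations run across genes, which are not independent replicates. Ratios are log2 ratios of CPM, UMI counts scaled to the same class total, within a class of nuclei, and a ratio given as "at least" had under 3 UMIs in the lower library, counted as 3. Class names stand for clusters that resemble a cell type by markers fixed beforehand. Gene symbols from families of near-identical copies, such as H2-T, H2-Q, Pydc and Hspa1a with Hspa1b, are uncertain at the level of the single copy.

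Human APOE (ENSG00000130203), which carries cholesterol-rich lipoprotein particles between brain cells and is the floxed gene, was read first in every library. In astrocytes it stood at 12715 CPM in FE3 and 12258 in FE4, at 16251 in TAFE3_oil and 18244 in TAFE4_oil. It stood at 5271 [5104, 5441] in TAFE3_tam and 5099 [4898, 5306] in TAFE4_tam. In microglia it was 1938 CPM in FE3, 1784 in FE4, 16637 in TAFE3_oil, 15517 in TAFE3_tam, 23545 in TAFE4_oil and 21110 in TAFE4_tam. Mouse Apoe (ENSMUSG00000002985) followed the human gene in astrocytes, with 1478, 1264, 1445, 428, 1731 and 541 CPM in FE3, FE4, TAFE3_oil, TAFE3_tam, TAFE4_oil and TAFE4_tam. Mouse Apoe made up between 7.51% and 15.5% of the Apoe and APOE UMIs in each class and library. Whether the UMIs under mouse Apoe came from a mouse gene or from the human transcript was not settled. The Apoe values below therefore add no result separate from APOE.

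Prnp, whose promoter drives many tau transgenes, stood at 172 and 129 CPM in excitatory neurons of FE3 and FE4. It was 281 and 277 in TAFE3_oil and TAFE3_tam, and 300 and 297 in TAFE4_oil and TAFE4_tam. In astrocytes Prnp was 319 and 286 CPM in FE3 and FE4 and between 558 and 682 in the TAFE libraries. Mouse Mapt, which codes for tau, was 229 and 212 CPM in excitatory neurons of FE3 and FE4 and between 304 and 350 in the TAFE libraries. Whether Mapt and Prnp counts hold reads of the tau transgene was not settled. Aldh1l1, the gene whose promoter names the Cre line, was 71.6 and 62.7 CPM in astrocytes of FE3 and FE4. It was 95.6, 85.8, 73.8 and 112 in TAFE3_oil, TAFE3_tam, TAFE4_oil and TAFE4_tam. The label check list had medians in microglia of 1.85 in TAFE3_oil against FE3 and 2.27 in TAFE4_oil against FE4, each over 4 members without Aldh1l1, which had too few UMIs there. For tamoxifen against oil it had -0.10 over 4 members and -0.16 over 5. Y-linked Ddx3y ran from 63.8 to 80.8 CPM over all nuclei and X-inactivation RNA Xist from 1.92 to 7.32. The sex-linked list stayed between -0.32 and 0.11 in the 7 comparisons.

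Mitochondrial RNA split the libraries. Its median share per barcode was 3.23% in FE3, 2.01% in TAFE3_oil, 2.81% in TAFE3_tam and 2.35% in TAFE4_oil, but 0.625% in FE4 and 0.695% in TAFE4_tam. The mitochondrially encoded list (13 genes) was -1.57 in FE4 against FE3 and 1.34 in TAFE4_oil against FE4. It was -1.24 in TAFE4_tam against TAFE4_oil and -1.26 in TAFE4_tam against TAFE3_tam, and lay between -0.55 and 0.33 in the other 3 comparisons. Ribosomal protein genes in oligodendrocytes followed the same split, with -0.81, 0.98, -0.63 and -0.63 in those 4 comparisons against -0.08, 0.21 and 0.23 in the rest. The median of long nuclear RNAs (6 genes) stayed between -0.10 and 0.05, which does not show that each member did. The median of all genes in excitatory neurons was 0.25 in TAFE4_oil against FE4, 0.13 in TAFE4_oil against TAFE3_oil and -0.13 in FE4 against FE3, shifts that scaling by trimmed means of M values took away.

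**Figure D1:**
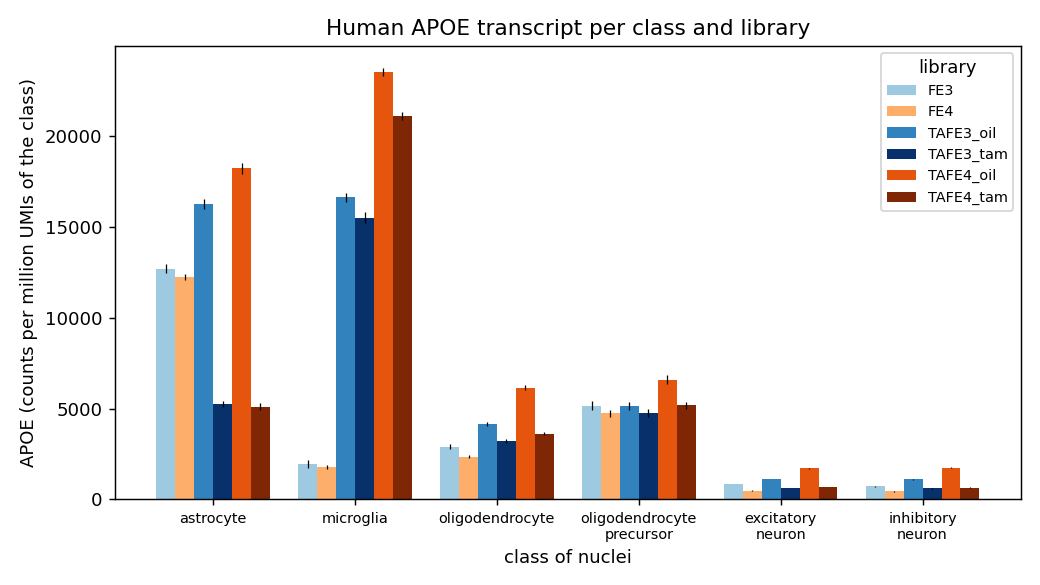
APOE in CPM by class of nuclei and library, with 95% Poisson intervals. Astrocytes of TAFE3_tam and TAFE4_tam stood at 5271 and 5099 CPM, against 16251 and 18244 with oil.

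Tau mice were compared with mice without tau in the same APOE background (TAFE3_oil against FE3, TAFE4_oil against FE4). The question was which nuclei and genes differ where tau, Cre and oil are present together. The mix of regions differed as well. Subicular or cortical neurons were 12.4% of nuclei in FE3 and 33.1% in TAFE3_oil, and 10.7% in FE4 and 39.8% in TAFE4_oil. Glia and inhibitory neurons were not split by region, so regional differences cannot be told apart from tau, Cre and oil in them. That limit holds for their correlations between backgrounds too. Microglia were 8.94% [8.40, 9.50] of nuclei in TAFE3_oil against 1.46% [1.22, 1.73] in FE3, and 9.47% [8.96, 10.0] in TAFE4_oil against 3.76% [3.46, 4.09] in FE4. Microglial Spp1, a secreted phosphoprotein of phagocytes, was higher by at least 5.02 and by 6.05 [4.69, 7.93]. P2ry12, the purine receptor of resting microglia, was lower by -1.73 [-2.31, -1.13] and -3.01 [-3.44, -2.59]. Astrocytes had more Serpina3n, Vim and Gfap, and hippocampal neurons were a smaller share of nuclei. Across genes the 2 backgrounds correlated by 0.739 in pooled excitatory neurons, whose mix of subtypes differed, and within them by 0.583 in subicular or cortical, 0.420 in CA1, 0.374 in CA2 or CA3 and 0.365 in granule neurons. The value was 0.496 in astrocytes, 0.350 in microglia and 0.358 in oligodendrocytes, and for genes with at least 500 UMIs 0.668, 0.562 and 0.468.

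The microglia share was higher by 2.61 [2.35, 2.89] and 1.33 [1.18, 1.48]. Without the mitochondrial filter the values were 1.85 and 1.67, with at least 1000 UMIs per nucleus 2.01 and 2.88, and with at most 1% mitochondrial UMIs 0.0034 in TAFE4_oil against FE4. Astrocytes were 5.42% of nuclei in FE3, 6.60% in FE4, 3.33% in TAFE3_oil and 2.64% in TAFE4_oil, ratios of -0.70 [-0.91, -0.50] and -1.32 [-1.51, -1.14]. Those became -0.88 and -0.54 without the filter, and 1.43 and -2.55 with at most 1% mitochondrial UMIs. The filter removed 68.6% of microglia in FE3 and 38.4% in TAFE3_oil, and 9.14% in FE4 and 37.9% in TAFE4_oil. Oligodendrocyte precursors were 2.64%, 2.99%, 2.67% and 2.66% of nuclei in FE3, FE4, TAFE3_oil and TAFE4_oil.

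Dentate granule neurons were 24.3% of nuclei in FE3 and 23.4% in FE4 against 7.03% in TAFE3_oil and 5.09% in TAFE4_oil, ratios of -1.79 [-1.91, -1.67] and -2.20 [-2.33, -2.08]. CA1 neurons were lower by -1.62 [-1.77, -1.48] and -2.34 [-2.52, -2.16], and CA2 or CA3 neurons by -1.52 [-1.71, -1.32] and -1.66 [-1.88, -1.44]. Subicular or cortical excitatory neurons were higher by 1.41 [1.32, 1.51] and 1.90 [1.82, 1.98], and inhibitory neurons by 0.33 [0.20, 0.47] and 0.88 [0.76, 0.99]. Unnamed cluster 6, in which excitatory markers were detected, stood outside the named excitatory classes. It was 9.79% of nuclei in FE3 and 3.26% in TAFE3_oil, and 7.83% in FE4 and 2.48% in TAFE4_oil. The rise of subicular or cortical neurons would be smaller with it included. Within the 3 hippocampal classes together, granule neurons made up 50.9% in FE3, 56.3% in FE4, 47.4% in TAFE3_oil and 54.3% in TAFE4_oil. T cell nuclei numbered 0 in FE3 and 3 in FE4, and 14 in TAFE3_oil and 18 in TAFE4_oil. Blood genes over all nuclei were higher by 2.83 [2.51, 3.05] and 2.49 [2.12, 2.68].

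**Figure D2:**
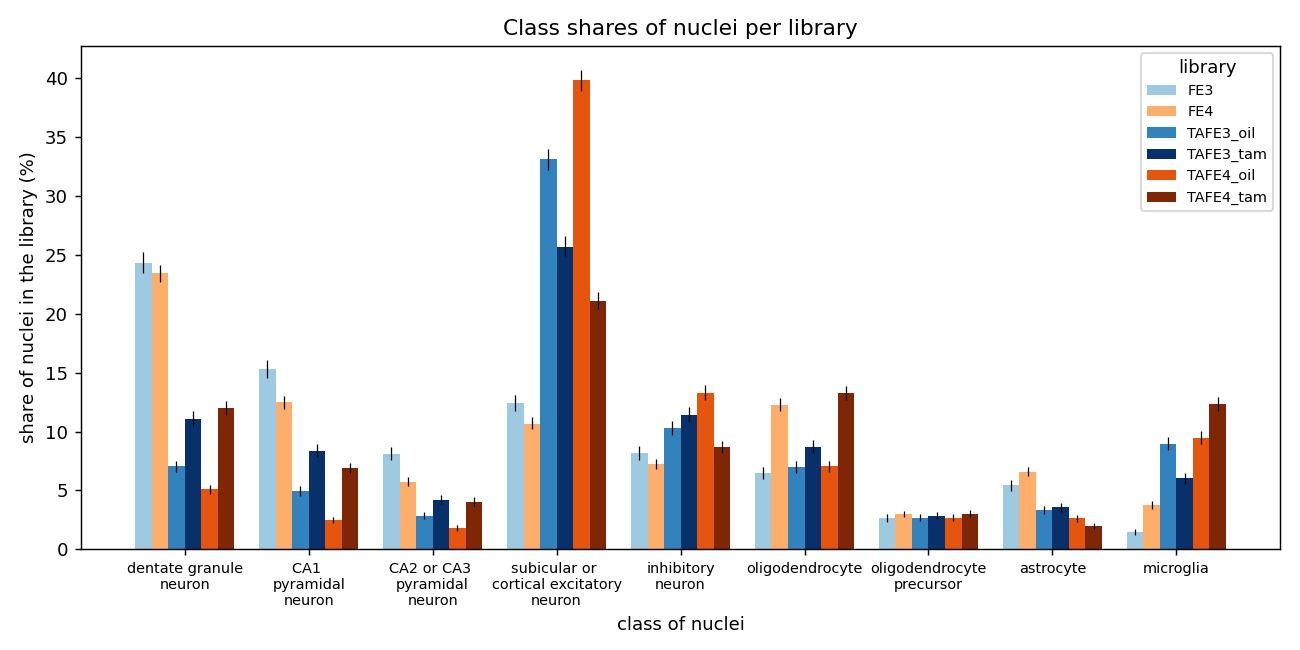
Share of nuclei in percent by class and library, with 95% Clopper-Pearson intervals. Granule neurons were 24.3% and 23.4% in FE3 and FE4 against 7.03% and 5.09% in TAFE3_oil and TAFE4_oil.

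In microglia the disease-associated genes had a median of 1.58 [1.35, 1.74] in TAFE3_oil against FE3 (37 higher, 1 lower) and 1.28 [1.17, 1.67] in TAFE4_oil against FE4 (42 higher, 0 lower). Lyz2, a lysozyme, was higher by 4.18 [2.95, 5.81] and 3.45 [2.81, 4.17], Lilrb4 by at least 3.64 and by 3.17, and Axl, a receptor for dying cells, by 2.78 and at least 4.11. Lpl, which releases fatty acids from lipoproteins, was higher by 3.22 and 1.93, and Cd63, a lysosomal membrane protein, by 1.80 and 1.89. Human APOE was higher by 3.1 [2.95, 3.26] and 3.72 [3.63, 3.82], and mouse Apoe by 2.96 [2.53, 3.43] and 3.97 [3.69, 4.26]. Trem2, the lipid receptor that microglia need for this state, differed by 0.62 [0.33, 0.92] and 0.05 [-0.12, 0.22]. Neuronal transcripts in microglia, a measure of free RNA, were -0.84 in TAFE3_oil against FE3 and 0.38 in TAFE4_oil against FE4.

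Homeostatic microglia genes had medians of -0.65 [-0.76, -0.43] (2 higher, 25 lower) and -1.22 [-1.44, -1.08] (1 higher, 28 lower), beside 0.29 and -0.39 for genes enriched in microglia as a whole. Selplg was lower by -1.68 [-2.05, -1.31] and -2.71 [-3.00, -2.42], P2ry13 by -1.66 and -2.01, Ltc4s, which makes leukotriene C4, by -1.51 and -1.88, and Ecscr by -2.51 and -3.31. Mef2c went against its list with 0.80 and 0.45. Lysosome and phagocytosis genes had medians of 0.65 [0.50, 0.83] and 0.23 [0.08, 0.30]. Complement genes in microglia had medians of 0.64 [0.41, 0.78] and 0.04 [-0.04, 0.12]. C4b among them was higher by at least 2.65 and by 2.57.

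Antigen presentation and interferon genes were higher in microglia of both tau libraries. MHC class I genes had medians of 1.26 [1.11, 1.65] (15 higher, 0 lower) and 1.16 [0.84, 1.62] (15 higher, 1 lower), with H2-K1 at 2.5 [1.94, 3.13] and 2.35 [2.02, 2.70]. MHC class II genes had 2.38 [1.75, 2.65] and 0.98 [0.59, 1.44], the latter -0.28 with at least 1000 UMIs per nucleus. Cd74, the chaperone of MHC class II, was higher by 2.75 [1.90, 3.76] and 2.22 [1.76, 2.71]. Interferon-response genes had 1.14 [0.74, 1.26] (29 higher, 0 lower) and 1.11 [0.85, 1.34] (31 higher, 2 lower). With members of at least 100 UMIs the first was 2.02, and with at least 1000 UMIs per nucleus the second was 0.64.

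In astrocytes the reactive genes had medians of 1.58 [1.37, 2.02] (24 higher, 2 lower) and 1.51 [1.29, 1.74] (25 higher, 3 lower). Serpina3n, a secreted protease inhibitor, was higher by at least 4.85 and by 3.47 [2.49, 4.56], and Cxcl5, a chemokine, by 2.96 and 3.72. Vim, an intermediate filament, was higher by 3.16 [2.75, 3.59] and 2.35 [2.06, 2.66], and Gfap by 2.40 [2.22, 2.59] and 2.02 [1.88, 2.16]. Ifitm3, an antiviral membrane protein, was higher by 2.93 [2.20, 3.76] and 2.55 [2.0, 3.12], in an interferon list at 1.67 [1.16, 2.12] and 1.37 [1.18, 1.82]. MHC class I genes in astrocytes had 1.27 [0.79, 1.64] and 1.26 [1.01, 1.80], with B2m at 2.24 and 2.28. Lower in both were Zfhx4 at -1.24 and -1.83, Msx1 at -1.79 and -1.11, Prr5 at -1.20 and -1.25, Garem at -1.19 and -1.26 and Adamts9 at -1.19 and -0.95.

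Complement genes in astrocytes had medians of 1.54 [1.30, 2.0] and 1.59 [1.21, 2.31], all 8 members higher in each. C4b was higher by 1.39 [1.15, 1.63] and 1.41 [1.21, 1.61] and Clu by 1.0 and 0.99, while C1qa, a gene of microglia, was higher by 2.32 and 3.32 beside microglia shares higher by 2.61 and 1.33. Cholesterol synthesis genes in astrocytes had -0.32 [-0.58, -0.17] (6 higher, 17 lower) and -0.22 [-0.36, -0.03] (9 higher, 15 lower), with Sqle at -1.08 [-1.59, -0.59] and -0.35 [-0.79, 0.06], and Idi1 at -0.90 and -0.48. With doublets kept the median in TAFE4_oil against FE4 was 0.027. Lipid transport genes had 0.03 and 0.27 in astrocytes and 0.36 [0.10, 0.66] and 0.55 [0.21, 0.65] in microglia, with Abca1, the cholesterol pump, at 1.13 and 1.32 in astrocytes. Homeostatic astrocyte genes had -0.07 [-0.22, -0.01] and 0.06 [-0.01, 0.18], the first 0.18 with doublets kept. Genes of synapse organisation and engulfment had -0.03 and 0.26 [0.07, 0.39], the second 0.052 with TMM factors.

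In oligodendrocytes C4b, a complement protein, was higher by 3.71 [3.23, 4.24] and 3.42 [3.18, 3.66], and Cdkn1a, a cell-cycle inhibitor under p53, by at least 3.11 and by 3.59 [2.45, 4.98]. Parp3 was higher by 2.70 and 3.91 and Fcho1 by 3.01 and 2.43. The reactive oligodendrocyte list had 0.50 [0.40, 0.98] (22 higher, 5 lower) and 1.28 [1.01, 1.48] (25 higher, 6 lower), MHC class I 1.19 and 1.95 [1.65, 2.39], and interferon-response genes 1.04 and 0.89. Sgk1, a kinase under glucocorticoids, was lower by -1.0 [-1.41, -0.60] and -1.78 [-2.08, -1.48], Polr3e by -1.12 and -1.97 and Dcp1b by -0.88 and -1.40. Myelin genes had -0.14 [-0.22, -0.06] and -0.11 [-0.18, -0.02]. Cholesterol synthesis genes in oligodendrocytes had -0.29 and -0.03.

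Neurons were read within subtypes, as the mix of excitatory subtypes differed between libraries. In granule neurons Tnrc6c, of the microRNA silencing complex, was higher by 1.06 [0.96, 1.15] and 1.13 [1.04, 1.23], Otulin, a deubiquitinase, by 1.17 and 1.10 and Abcb10 by 1.12 and 0.97. Sec1 at -1.17 and -1.33, Ntn5 at -1.52 and -1.07, Ybx2 at -1.04 and -1.14 and Elp4 at -0.84 and -1.29 were lower. In CA1 neurons Cdk5r1, the activator of the tau kinase Cdk5, was higher by 1.14 [0.85, 1.42] and 1.24 [0.96, 1.52], Hapln4 by 1.13 and 1.81 and Lpl by 1.11 and 1.44. Crtac1, an extracellular matrix protein, was lower there by -1.49 [-1.83, -1.17] and -1.36 [-1.77, -0.98], and Gcnt2 at -1.83 and -1.12, P4ha2 at -1.07 and -0.99 and Fxyd5 at -0.93 and -1.97 were also lower.

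Immediate early genes, the first response to neuronal activity, had medians of 0.35 and 0.73 [0.43, 0.85] in granule neurons, 0.34 [0.21, 0.43] and 0.15 in CA1 and 0.08 and 0.65 in inhibitory neurons. Pooled excitatory neurons had 0.52 [0.45, 0.61] and 0.93 [0.85, 0.99], with Ier2 at 1.61 and 1.97. Postsynaptic genes had -0.08 and 0.06 in granule neurons, -0.17 [-0.21, -0.12] and 0.07 in CA1, and -0.12 and 0.17 in inhibitory neurons. Presynaptic genes had -0.11 and 0.18 in granule neurons, -0.11 and 0.04 in CA1, and in inhibitory neurons 0.29 in TAFE4_oil against FE4, with an interval of [-0.09, 0.03] in TAFE3_oil against FE3. With TMM factors the presynaptic and postsynaptic values in inhibitory neurons of TAFE4_oil against FE4 were 0.039 and -0.082, and the median of all genes there was 0.26 without them. p53 and DNA damage genes had 0.25 and 0.37 in granule neurons and 0.45 [0.28, 0.96] and 0.65 [0.42, 0.92] in oligodendrocytes. Cholesterol synthesis genes had -0.31 and 0.10 in granule neurons and -0.28 and 0.05 in CA1.

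Heat shock genes had medians of 0.43 and 0.81 in astrocytes, 0.07 and 0.75 in microglia, 0.14 and 0.79 in oligodendrocytes and 0.16 and 0.84 in granule neurons. Oxidative phosphorylation genes had 0.24 and 1.01 in astrocytes, 0.14 and 0.79 in microglia and 0.02 and 0.92 in granule neurons. These stood beside ribosomal protein medians of 0.17 and 1.03 in astrocytes and mitochondrial medians of -0.55 and 1.34. Unfolded protein and integrated stress response genes had 0.21 and 0.49 in astrocytes and -0.19 and -0.16 in microglia, the last 0.27 with doublets kept. Genes that parted between the backgrounds included Ap2s1 in astrocytes at -1.04 and 1.60, Cpsf7 at -1.60 and 0.63, and Cdh23 in microglia, at least 1.03 and -1.22. Zfp710 in microglia stood at 0.92 and -1.70 and Asns, which makes asparagine, at -1.08 and 1.67. Ap2s1 was 0.044 in TAFE3_oil against FE3 without the mitochondrial filter, and Cdh23 was 0.40 in TAFE4_oil against FE4 with at least 1000 UMIs per nucleus.

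**Figure D3:**
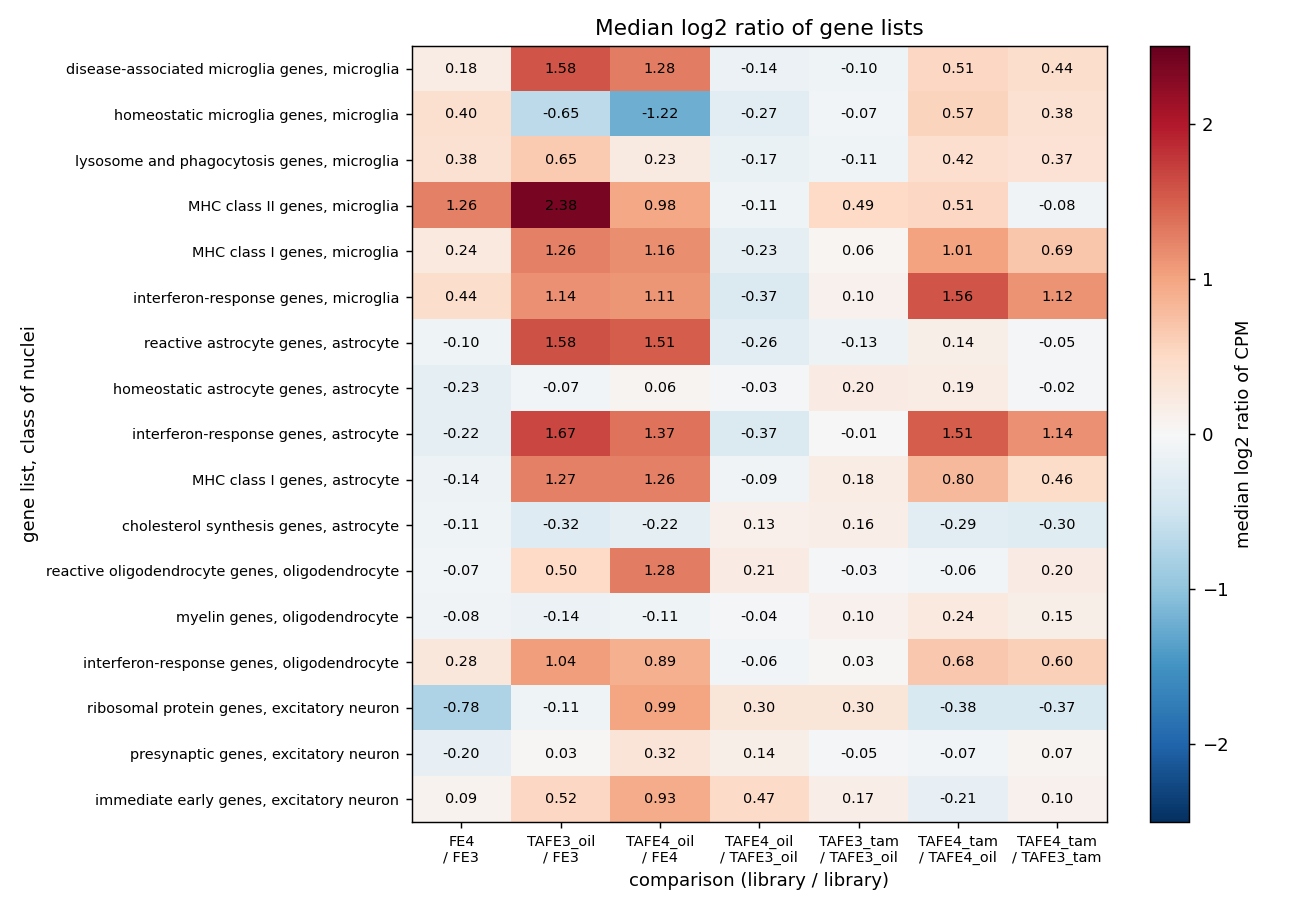
Median log2 ratio of gene lists by class and comparison, drawn as colours with the value printed in each cell and without intervals. Disease-associated genes in microglia stood at 1.58 and 1.28 in the tau comparisons and at -0.10 and 0.51 for tamoxifen against oil.

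Tamoxifen libraries were compared with oil libraries of the same genotype (TAFE3_tam against TAFE3_oil, TAFE4_tam against TAFE4_oil), to ask what differs in tau mice when astrocytes hold less APOE. Astrocytic APOE was lower by -1.62 [-1.68, -1.57] and -1.84 [-1.90, -1.78]. Granule, CA1 and CA2 or CA3 neurons were a larger share of nuclei in both. Nuclei of the subicular or cortical class per oligodendrocyte precursor were fewer with tamoxifen, at 9.01 in TAFE3_tam against 12.4 in TAFE3_oil. They stood at 6.98 in TAFE4_tam against 14.98 in TAFE4_oil. The count left out an unnamed cluster with excitatory markers, which was a larger share with tamoxifen. A smaller part of cortex in the tissue taken stays open as a source of the larger hippocampal shares and was not tested. Microglial Cxcl10, a chemokine that draws T cells, was higher in both, by 2.16 [1.47, 2.90] and 2.49 [1.94, 3.1], while the interferon list as a whole was at 0.10 [-0.14, 0.23] with APOE3 and 1.56 [1.42, 1.72] with APOE4, a difference that was not tested. The APOE3 value of interferon-response genes in microglia was -0.23 with at least 1000 UMIs per nucleus and -0.25 with members of at least 100 UMIs. Across genes the 2 backgrounds correlated by 0.078 in astrocytes, -0.0056 in microglia and 0.0070 in oligodendrocytes, and for genes with at least 500 UMIs by 0.154, -0.133 and -0.0933. The microglia value was 0.126 with doublets kept. Pooled excitatory neurons, whose mix of subtypes differed, had 0.240, and within them subicular or cortical neurons had 0.124, CA1 0.061, CA2 or CA3 0.048 and granule neurons 0.031.

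At 1000 UMIs per nucleus, astrocyte nuclei had a median of 13 APOE UMIs in TAFE3_oil and 2 in TAFE3_tam, and 15 in TAFE4_oil and 1 in TAFE4_tam. The share of astrocyte nuclei with an APOE UMI was 99.7%, 78.8%, 100% and 77.3% in that order. Granule neurons, read as background, had 78.1%, 55.6%, 84.1% and 57.2%, with median depths before thinning of 2365.5, 2340, 2683.5 and 2230 UMIs against 1819, 1622, 1903 and 1625.5 in astrocytes. Above the 90th percentile of granule neurons of their own library lay 90.1%, 40.7%, 90.3% and 33.8% of astrocyte nuclei. In other classes APOE with tamoxifen and oil was 3202 and 4149 CPM in oligodendrocytes and 811 and 1402 in granule neurons of the APOE3 background. In the APOE4 background it was 3617 and 6155 CPM, and 862 and 1981. Vascular leptomeningeal cells had 3166 and 6883 CPM with APOE3, and 3125 and 7295 with APOE4.

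Granule neurons were 11.1% of nuclei in TAFE3_tam against 7.03% in TAFE3_oil, and a larger share in TAFE4_tam than the 5.09% of TAFE4_oil, ratios of 0.66 [0.52, 0.80] and 1.24 [1.10, 1.38]. CA1 neurons were higher by 0.75 [0.59, 0.91] and 1.48 [1.29, 1.68], and CA2 or CA3 neurons by 0.57 [0.35, 0.79] and 1.16 [0.93, 1.40]. Subicular or cortical neurons were lower by -0.37 [-0.44, -0.29] and -0.92 [-0.99, -0.85]. Unnamed cluster 6, outside that class, was 3.26% in TAFE3_oil and 7.11% in TAFE3_tam, and 2.48% in TAFE4_oil and 4.31% in TAFE4_tam. Oligodendrocytes were higher by 0.32 [0.18, 0.46] and 0.92 [0.80, 1.04], the first -1.37 with at most 1% mitochondrial UMIs. Microglia differed by -0.57 [-0.72, -0.42] and 0.38 [0.27, 0.49], values that were -0.051 and -0.0022 without the mitochondrial filter, -0.33 and 0.20 with at least 1000 UMIs, and in the second 1.87 with at most 1% mitochondrial UMIs. Astrocytes differed by 0.10 [-0.12, 0.31] and -0.44 [-0.68, -0.19], 0.31 and -1.07 without the filter and -1.36 and 0.98 with at most 1% mitochondrial UMIs. T cell nuclei numbered 4 in TAFE3_tam and 14 in TAFE3_oil, and 47 in TAFE4_tam and 18 in TAFE4_oil.

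In astrocytes, mouse Apoe was lower by -1.76 [-1.94, -1.57] and -1.68 [-1.88, -1.48], Nfe2l2, which governs the antioxidant response, by -1.0 and -1.20, Hnrnpa1 by -0.95 and -1.40 and Pcp4 by -0.91 and -0.93. Sox1 was higher by 0.95 [0.22, 1.70] and 0.93 [0.24, 1.62], Acbd4 by 0.92 and 0.97 and Cyp7b1, which hydroxylates oxysterols, by 0.79 [0.23, 1.37] and 1.16 [0.36, 1.98]. Tap2, the peptide transporter for MHC class I, was higher by 0.76 and 0.72 and H2-T23 by 0.81 and 1.42. Homeostatic astrocyte genes had medians of 0.20 [0.14, 0.26] (30 higher, 7 lower) and 0.19 [0.14, 0.28] (27 higher, 10 lower), beside 0.19 and 0.14 for genes enriched in astrocytes as a whole. Slc6a11, a GABA transporter, stood at 0.68 and -0.07. Reactive astrocyte genes had -0.13 [-0.28, -0.01] and 0.14 [0.06, 0.43], with Vim at -0.53 and -0.44. Without a minimum number of UMIs the first was -0.29, and as a mean over nuclei the second was 0.049.

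Genes of synapse organisation and engulfment in astrocytes had 0.32 [0.13, 0.41] (20 higher, 6 lower) in TAFE3_tam against TAFE3_oil and 0.03 [-0.09, 0.17] in TAFE4_tam against TAFE4_oil, with Mertk, an engulfment receptor, at -0.32 and 0.54. Cholesterol synthesis genes in astrocytes had 0.16 [-0.13, 0.26] and -0.29 [-0.55, -0.04], and lipid transport genes 0.18 [0.06, 0.30] and 0.06. Complement genes had -0.09 and 0.09. Genes that parted between the backgrounds in astrocytes were Cxcl10 at -0.43 [-1.37, 0.49] and 3.62 [3.03, 4.27], H2-T22 at -0.72 and 1.70 and Lgals3bp at 0.04 and 1.80. The other way were Ephx2, which opens lipid epoxides, at 1.19 [0.44, 1.98] and -1.52 [-3.08, -0.22], Myoc at -0.06 and -2.27 [-3.06, -1.56] and Rab1 at 1.20 and -0.77. The interferon list in astrocytes had -0.01 [-0.24, 0.16] and 1.51 [1.31, 1.88], and MHC class I genes 0.18 and 0.80 [0.66, 1.32].

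In microglia Oasl2, an interferon-induced gene, was higher by 1.05 [0.10, 2.03] and 2.10 [1.49, 2.75], Siglec5 by 1.27 and 1.19, Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol, by 1.12 and 1.29 and Il4i1 by 1.49 and 1.0. Cryab, a small heat shock protein, was lower by -0.94 in each, Pop7 by -1.24 and -0.94 and Polr2m by -0.86 and -1.03. Gabrd and Kcnf1, both neuronal genes, were lower by -0.81 and -0.99 and by -0.98 and -0.89, beside neuronal transcripts in microglia at 0.19 and -0.81. MHC class II genes had medians of 0.49 [0.25, 0.65] and 0.51 [0.35, 0.68], with Cd74 at 0.62 [0.43, 0.81] and 0.64 [0.49, 0.79]. MHC class I genes had 0.06 and 1.01 [0.83, 1.10] (16 higher, 0 lower). In the interferon list of TAFE4_tam against TAFE4_oil 45 genes were higher and 0 lower, among them Samd9l at 2.66 [1.84, 3.59], with Stat2 at -0.55 and Ifitm3 at -0.61 in TAFE3_tam against TAFE3_oil.

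Disease-associated genes had medians of -0.10 [-0.20, -0.02] (17 higher, 25 lower) and 0.51 [0.39, 0.55] (35 higher, 8 lower), and homeostatic genes -0.07 and 0.57 [0.51, 0.72] (28 higher, 1 lower). Genes enriched in microglia as a whole had -0.04 and 0.76. With doublets kept the disease-associated values were 0.0011 and 0.24, and as a mean over nuclei the second was 0.19. Lysosome genes had -0.11 [-0.18, -0.04] and 0.42 [0.37, 0.48], and complement genes -0.14 and 0.46, with the lysosome value 0.0072 in TAFE3_tam against TAFE3_oil with doublets kept. In TAFE4_tam against TAFE4_oil P2ry12 stood at 1.37 [0.96, 1.80], Sall1, a microglial identity factor, at 1.45, Ccl6 at 1.24 and Gpnmb at -0.67. APOE in microglia differed by -0.10 and -0.16, the first 0.022 with doublets kept and the second 0.15 with at least 1000 UMIs per nucleus. Ccl12, a chemokine for monocytes, stood at -0.49 [-0.97, -0.03] and 2.13 [1.76, 2.51], Piezo1, a mechanosensitive channel, at -1.03 and 1.75, Fam111a at -1.22 and 1.26 and Ccdc85b at 0.96 and -1.04. Lipid transport genes had 0.07 and 0.06.

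**Figure D4:**
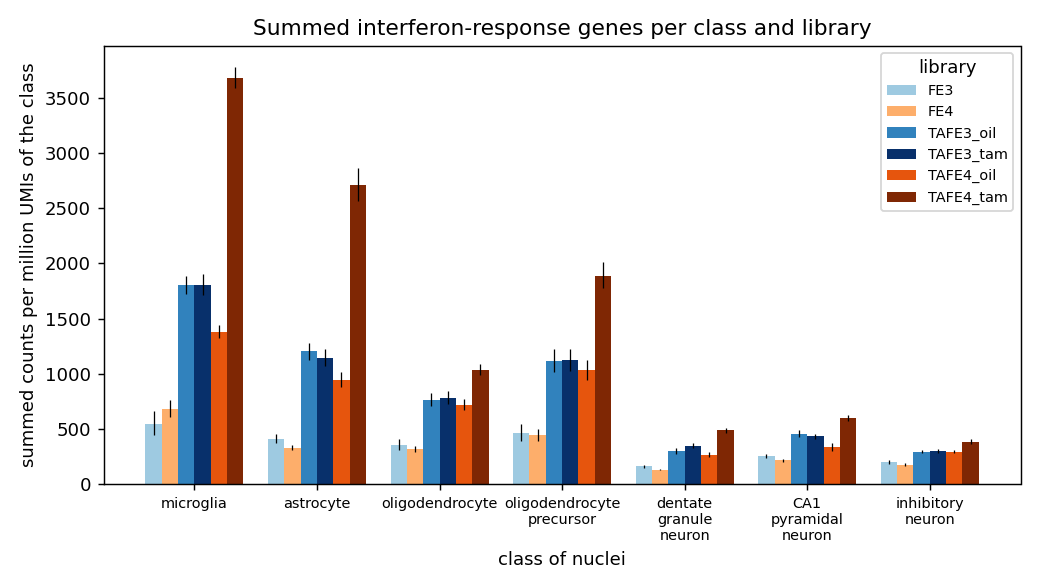
Summed CPM of interferon-response genes by class and library, with 95% Poisson intervals. TAFE4_tam exceeded TAFE4_oil by 2302 in microglia, 1764 in astrocytes, 316 in oligodendrocytes and 223 in granule neurons.

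In oligodendrocytes Apoc1, an apolipoprotein, was higher by 1.95 [0.81, 3.27] and 1.76 [1.03, 2.57]. Clic1 was lower by -1.04 and -1.01, Mrpl42 by -0.99 and -1.23, Phb, a mitochondrial scaffold, by -0.91 and -0.94, Psmd8 by -0.87 and -0.91 and Anxa5 by -0.99 and -0.85. Myelin genes had medians of 0.10 and 0.24 [0.19, 0.30] (26 higher, 4 lower), beside 0.062 and 0.23 for genes enriched in oligodendrocytes as a whole. Cldn11 stood at -0.33 and 0.52, and reactive oligodendrocyte genes had -0.03 and -0.06. Interferon-response genes had 0.03 and 0.68 [0.45, 1.05], the second -0.22 [-0.63, 0.017] over 14 members among nuclei with at most 1% mitochondrial UMIs, and MHC class I genes 0.11 and 0.47. Cholesterol synthesis genes had -0.18 and -0.03.

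In CA1 neurons Crtac1 was higher by 1.15 [0.81, 1.5] and 0.83 [0.41, 1.27], Egr4 by 0.78 and 0.72, Rasd1 by 0.78 and 0.92 and Cpne7, a calcium-dependent membrane protein, by 0.69 [0.59, 0.79] and 0.66 [0.54, 0.79]. Slc35f6 was lower by -0.70 and -1.02 and Akirin1 by -0.66 and -0.84. In granule neurons Aar2 was higher by 0.79 and 0.97 and Eftud1 by 0.89 and 0.69, while Net1 was lower by -0.80 and -0.69 and Hist1h2bc by -0.59 and -0.96. Postsynaptic genes had 0.05 and 0.18 [0.14, 0.26] in CA1, 0.04 and 0.14 [0.09, 0.20] in granule and 0.04 and -0.03 in inhibitory neurons. Immediate early genes had 0.16 and 0.31 [0.19, 0.47] in CA1, 0.06 and -0.26 in granule and 0.17 and -0.29 in inhibitory neurons. Presynaptic genes had 0.03 and 0.08 in CA1 and 0.03 and 0.01 in granule neurons, and cholesterol synthesis genes 0.28 [0.06, 0.42] and -0.03 in granule neurons.

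Heat shock genes had medians of -0.14 and -0.51 [-0.70, -0.31] in astrocytes, -0.23 and -0.36 in microglia, -0.24 and -0.45 in oligodendrocytes and -0.08 and -0.29 in granule neurons. Oxidative phosphorylation genes had 0.13 and -0.51 in astrocytes and 0.04 and -0.66 in oligodendrocytes, beside mitochondrial medians of 0.33 and -1.24. Unfolded protein genes had 0.03 and 0.02 in astrocytes and -0.13 and 0.23 in microglia. p53 genes had -0.07 and -0.23 in astrocytes and -0.22 and -0.38 in oligodendrocytes. Blood genes over all nuclei had -0.78 and 0.52.

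Across genes, tamoxifen ratios were set against tau ratios of the other background, which share no library. Tau in APOE3 against tamoxifen in APOE4 gave -0.218 in astrocytes, 0.155 in microglia, -0.130 in oligodendrocytes, -0.112 in granule and -0.182 in CA1 neurons, the microglial value -0.012 with doublets kept. Tau in APOE4 against tamoxifen in APOE3 gave -0.126, -0.103, -0.081, -0.140 and -0.183. Ratios that share the oil library gave -0.427 in astrocytes of APOE3 and -0.489 of APOE4, where simulated counts without any difference gave -0.489 and -0.525. In microglia these were -0.346 and -0.373 against -0.235 and -0.343.

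APOE4 was compared with APOE3 without tau (FE4 against FE3) and with tau and oil (TAFE4_oil against TAFE3_oil), to ask which genes differ with the allele in both. In oligodendrocytes Klk6, a protease, was lower with APOE4 by -1.61 [-2.93, -0.30] and -1.51 [-2.22, -0.84]. In granule neurons Mid1, a ubiquitin ligase, was higher by 1.65 [1.32, 2.0] and 1.47 [0.76, 2.23]. In tau mice, APOE4 microglia held more APOE than APOE3 microglia, 23545 against 16637 CPM. Astrocytic APOE was 12258 CPM in FE4 and 12715 in FE3, a difference of -0.053 that was 0.061 with doublets kept.

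In astrocytes Kctd1 was lower by -1.02 [-1.84, -0.20] and -1.65 [-2.77, -0.64], Snx2, a sorting nexin, by -0.87 and -0.94, Gdf11 by -1.21 and -0.77 and Elovl6, which lengthens fatty acids, by -1.10 and -0.76. Flot2 was higher by 0.74 and 1.22, Aldh6a1 by 0.77 and 0.65 and Dynlt3 by 0.62 and 0.80. Homeostatic astrocyte genes had medians of -0.23 [-0.28, -0.18] (3 higher, 34 lower) and -0.03, beside -0.26 and 0.043 for genes enriched in astrocytes as a whole. Reactive astrocyte genes had -0.10 and -0.26 [-0.41, -0.16], with Serpina3n at -0.79 and Vim at -0.72 in TAFE4_oil against TAFE3_oil. That median was -0.081 without the mitochondrial filter. Complement genes in astrocytes had -0.70 [-0.95, -0.12] and -0.04, and cholesterol synthesis genes -0.11 and 0.13. Neuronal transcripts in astrocytes were at 0.58 and 0.25 and in microglia at -0.81 and 0.23.

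In microglia Ppip5k2, an inositol pyrophosphate kinase, was lower by -1.53 [-2.61, -0.46] and -0.85 [-1.32, -0.38], Znhit6 by -1.69 and -0.84 and Stat2 by -0.86 and -1.03. Lman2, a cargo receptor of the secretory path, was higher by 0.88 and 1.03, and Rp9 by 1.51 and 0.90, the first -0.43 with at least 1000 UMIs per nucleus. In TAFE4_oil against TAFE3_oil Ccl12 stood at -1.21 and Cst7, a protease inhibitor, at -0.71. Disease-associated genes had 0.18 [-0.02, 0.34] and -0.14 [-0.20, -0.07] (13 higher, 30 lower), homeostatic genes 0.40 [0.29, 0.55] and -0.27 [-0.36, -0.19], and lysosome genes 0.38 and -0.17, beside 0.42 and -0.21 for genes enriched in microglia as a whole. The disease-associated value in FE4 against FE3 was 0.43 with the top expected share of doublets left out and -0.16 with a pseudocount of 1 UMI. With doublets kept the disease-associated and lysosome values in TAFE4_oil against TAFE3_oil were 0.026 and 0.031. Interferon-response genes had 0.44 and -0.37 [-0.52, -0.20] (9 higher, 30 lower) and MHC class I genes 0.24 and -0.23, the latter 0.0089 with doublets kept. Complement genes had 0.43 and -0.20, and MHC class II genes 1.26 and -0.11.

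Ssbp1, of mitochondrial DNA upkeep, was higher in oligodendrocytes by 0.72 [0.24, 1.23] and 0.67 [0.20, 1.16], and Brap by 0.92 and 0.95. Tatdn3 was lower by -1.0 and -0.80 and Igfbp2 by -1.0 and -0.63. In granule neurons Bms1 was higher by 0.43 and 0.54, and Tspan15 was lower by -0.58 and -0.65, Hemk1 by -0.51 and -0.77 and Dgki, a diacylglycerol kinase, by -0.50 and -0.60. In CA1 neurons Fam189a1 was higher by 0.72 and 0.48 and Npas4, an activity-dependent transcription factor, by 0.61 [0.31, 0.91] and 0.55 [-0.02, 1.11]. Cbfa2t3 was lower there by -0.68 and -0.76 and Crocc by -0.55 [-0.70, -0.40] and -0.55 [-0.90, -0.21]. Immediate early genes had medians of 0.27 [0.05, 0.34] and 0.07 in CA1 and -0.06 and 0.20 [0.11, 0.45] in granule neurons. Cholesterol synthesis genes had -0.19 and -0.21 in CA1, presynaptic genes -0.20 and 0.06, and postsynaptic genes -0.18 and 0.04. Myelin genes had -0.08 and -0.04 and reactive oligodendrocyte genes -0.07 and 0.21 [0.06, 0.31].

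The microglia share was 1.37 [1.09, 1.65] higher in FE4 than in FE3 and differed by 0.08 [-0.04, 0.21] between TAFE4_oil and TAFE3_oil. The first was 0.28 without the mitochondrial filter and 2.72 with at most 1% mitochondrial UMIs. With at least 1000 UMIs they were -0.15 and 0.72. Astrocyte shares differed by 0.28 [0.12, 0.44] and -0.34 [-0.56, -0.11], which were -0.24 and 0.099 without the filter and 2.44 and -1.54 at the 1% limit. CA1 neurons were lower with APOE4 by -0.29 [-0.39, -0.19] and -1.01 [-1.22, -0.80], CA2 or CA3 neurons by -0.51 and -0.65 and granule neurons by -0.05 [-0.13, 0.02] and -0.47 [-0.62, -0.31]. Without the filter the first values were -0.053 for CA1 and -0.035 for CA2 or CA3 neurons. TAFE4_oil held more subicular or cortical neurons than TAFE3_oil (39.8% against 33.1%), so for the second values the tissue taken stays open.

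The tamoxifen libraries of the 2 alleles were compared last (TAFE4_tam against TAFE3_tam), to ask what differs with the allele when astrocytes hold less APOE. Astrocytic Cxcl10 was higher with APOE4 by 4.06 [3.36, 4.84] and Nfkbia, the inhibitor of NF-kB, by 0.95 [0.36, 1.56]. Microglial Pydc4 was higher by 2.24 [1.44, 3.15], Cd300lf by 1.71, Mx1, an antiviral GTPase, by 1.64 and AI607873 by 1.64. Interferon-response genes had medians of 1.12 [0.95, 1.25] (43 higher, 0 lower) in microglia, 1.14 [0.91, 1.46] (28 higher, 0 lower) in astrocytes and 0.60 [0.29, 0.82] in oligodendrocytes. T cell nuclei numbered 47 in TAFE4_tam and 4 in TAFE3_tam.

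Myoc was lower in astrocytes by -2.14 [-2.95, -1.42], Ndufb7 by -1.06 and Slc38a1, a glutamine transporter, by -0.95, with reactive astrocyte genes at -0.05 and MHC class I genes at 0.46. In microglia Otulin was lower by -1.95 [-2.5, -1.41], S100b by -1.44 and Tmem130 by -1.28, beside neuronal transcripts at -0.75. Disease-associated genes had 0.44 [0.37, 0.52] (40 higher, 2 lower), homeostatic genes 0.38, lysosome genes 0.37, complement genes 0.41, MHC class I genes 0.69 and MHC class II genes -0.08. The disease-associated value was 0.86 with at least 1000 UMIs per nucleus and 0.16 as a mean over nuclei. Clec7a, a glucan receptor, stood at 1.04, Fcgr1, a receptor for antibodies, at 1.07, Apoc1 at 1.58 and Apod at 1.42. Genes enriched in microglia as a whole had 0.57.

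Synj2 was higher in oligodendrocytes by 1.64, Clk3 by 1.59 and Stat3 by 1.41 [0.70, 2.18], and Pla2g7, which breaks down oxidised phospholipids, was lower by -1.24 and Atp5e by -1.15. Klk6 stood at 1.34. In granule neurons Otulin was lower by -1.48 [-2.0, -0.97], Scn9a, a sodium channel, by -1.27 and Pdzrn4 by -1.13, and Laptm4b was higher by 1.21 and Clmp by 0.97. In CA1 neurons Itga7, a laminin receptor, was higher by 1.57 and Inhba, an activin subunit, by 1.27, while Tnrc6c was lower by -0.99 [-1.09, -0.89] and Kit by -0.86. Immediate early genes in CA1 neurons had 0.32 [0.21, 0.44] and postsynaptic genes 0.13. Myelin genes had 0.15 and reactive oligodendrocyte genes 0.20.

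Microglia were a larger share with APOE4 by 1.04 [0.90, 1.17], a value of 0.15 without the mitochondrial filter and 2.66 with at most 1% mitochondrial UMIs. Astrocytes were a smaller share by -0.87 [-1.11, -0.63], a value of 0.81 with at most 1% mitochondrial UMIs. Oligodendrocytes were higher by 0.61 [0.49, 0.73]. CA1 neurons were lower by -0.28 [-0.42, -0.14], a value of 0.15 with doublets kept and 0.17 with components centred per library. Granule neurons differed by 0.11 and CA2 or CA3 neurons by -0.06.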

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

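The values of this paragraph were singled out because the same comparison took opposite signs in the APOE3 and APOE4 backgrounds with each counting interval away from 0, for lists in astrocytes, microglia, oligodendrocytes and pooled excitatory neurons and for genes named by their difference between backgrounds, and the differences were not tested. For tamoxifen against oil, disease-associated microglia genes stood at -0.10 with APOE3 and 0.51 with APOE4, lysosome genes in microglia at -0.11 and 0.42 and complement genes in microglia at -0.14 and 0.46. With doublets kept the disease-associated and lysosome values with APOE3 were 0.0011 and 0.0072, which ended the opposition. Reactive astrocyte genes stood at -0.13 and 0.14, and immediate early genes in pooled excitatory neurons at 0.17 and -0.21, against 0.16 and 0.31 in CA1 and 0.058 and -0.26 in granule neurons. Cholesterol synthesis genes in pooled excitatory neurons stood at -0.16 and 0.32 for tau, the second 0.047 with TMM factors, and at 0.13 and -0.24 for tamoxifen. For tau they stood at -0.31 and 0.096 in granule and -0.28 and 0.049 in CA1 neurons. Oxidative phosphorylation genes stood at 0.13 and -0.51 in astrocytes and 0.053 and -0.43 in excitatory neurons for tamoxifen, where 0.053 was -0.0015 with TMM factors. Ribosomal protein genes for tamoxifen stood at 0.18 and -0.48 in astrocytes, 0.11 and -0.24 in microglia, 0.23 and -0.63 in oligodendrocytes and 0.30 and -0.38 in excitatory neurons, and the astrocyte value of 0.18 was -0.017 without the mitochondrial filter. For tau the ribosomal protein genes stood at -0.081 and 0.98 in oligodendrocytes and -0.11 and 0.99 in excitatory neurons. Neuronal transcripts stood at 0.24 and -0.18 in astrocytes and -0.84 and 0.38 in microglia for tau, and at 0.19 and -0.81 in microglia for tamoxifen. Each of these oppositions of neuronal transcripts ended in an alternative: with doublets kept 0.24 was -0.48 and 0.38 was -0.14, and without the mitochondrial filter 0.24 was -0.078 and 0.19 was -0.0077. With the top expected share of doublets left out 0.24 was -0.054 and 0.19 was -0.068. Single genes were Ap2s1 in astrocytes at -1.04 and 1.60, the first 0.044 without the mitochondrial filter, and Cpsf7 at -1.60 and 0.63 for tau. For tamoxifen they were Ephx2 in astrocytes at 1.19 and -1.52, and in microglia Ccl12 at -0.49 and 2.13, Fam111a at -1.22 and 1.26 and Ccdc85b at 0.96 and -1.04.

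Nuclei of kinds outside the compared classes were singled out after the clusters were seen, each in the library that held the most of them, and differences in their number were not tested. TAFE4_tam held 47 T cell nuclei, 290 nuclei of cluster 20, led by the interferon genes Ifit1 and Rnf213, and 46 nuclei of cluster 29. Cluster 29 held 55 nuclei in all, with 0 in FE3 and 0 in FE4, and was led by Cyp3a25, Pck1, Abcc2, Slco1b2, Cps1 and Ahsg. Its leading genes held no marker of a listed class, and whether these nuclei came from brain was not settled. TAFE4_oil held 25 nuclei of cluster 28, led by the stress genes Tnfrsf12a and Hspa1a.

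The free RNA test in microglia was written before the result was seen, and the tests in astrocytes and oligodendrocytes and those on low mitochondrial nuclei were chosen after it. Interferon-response genes were higher in TAFE4_tam than in TAFE4_oil by a summed CPM 10.3 times that of granule neurons in microglia and 7.93 times in astrocytes, which argued against free RNA from interferon-rich nuclei as the source there. In oligodendrocytes the value was 1.42 times, which by the limit of the test went with free RNA. A response in the granule neurons themselves would give the same value. Depth also differed, with medians of 965 UMIs in oligodendrocytes and 2230 in granule neurons of TAFE4_tam. The test therefore cannot decide for oligodendrocytes. Among nuclei of at most 1% mitochondrial UMIs the list median was 2.06 [1.73, 2.18] in microglia, which argued against less cytoplasm as the source, and -0.22 [-0.63, 0.017] in oligodendrocytes, which went with it, on 61 nuclei of each class in TAFE4_oil against 801 and 1184 in TAFE4_tam and on 37 and 14 members. Biological sources such as infection, the allele or the loss of APOE stay open and were not tested.

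The tests on shares were chosen after the shares were seen. Without the mitochondrial filter the microglia share differed by -0.0022 in TAFE4_tam against TAFE4_oil and by 0.28 in FE4 against FE3, which went with unequal loss to the filter. For tau oil libraries against FE libraries the smaller value was 1.67, which argued against it. Nuclei of the subicular or cortical class per oligodendrocyte precursor were higher in tau oil libraries by at least 2.63 [2.19, 3.17] times. As written, this argued against loss of hippocampal neurons alone. The count left out unnamed cluster 6, in which excitatory markers were detected and which went the other way. Cluster 6 held 892 nuclei in FE3 and 344 in TAFE3_oil, and 1124 in FE4 and 300 in TAFE4_oil. If its nuclei are cortical the fold is smaller, so the argument holds only for the named class. A larger part of cortex in the tissue taken, with or without loss of neurons, stays open, since the 6 hippocampal share ratios at or under -1.52 only restated the pattern and decided nothing.

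The test on APOE per nucleus was written before the result was seen, and a shared background was added after it. Astrocyte nuclei above the background of their own library held a median of 46.7% of the oil value in TAFE3_tam and 43.8% in TAFE4_tam. As written, with a limit of 60%, this argued against loss in a part of the nuclei with the rest at the oil level. That background was 2 UMIs with tamoxifen and 3 or 4 with oil, which let lower nuclei in with tamoxifen, and at a background shared by each pair the values were 73.3% and 68.8%, so the test was set to undecided after the fact. Read afterwards, the 90th percentile of APOE UMIs was 17.2 in TAFE3_tam against 32 with oil, and 14.2 in TAFE4_tam against 34. Medians differed more, at 2 against 13 and 1 against 15, which argued against an even loss in all nuclei. Uneven partial loss per nucleus and full loss in a part of the nuclei stay open.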

How the results depend on the processing

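Each group held 1 library, so values were not set against variation between animals. No paired analysis was possible because no labels tie libraries to litters or animals. Depth limits the rarer classes, with 133 microglia in FE3 and 242 astrocytes in TAFE4_tam, and a median of 884.5 UMIs per microglia nucleus. The alternative by barcode suffix was not run, as each matrix holds 1 suffix. The runs added after the data were seen were named above. For correlations they included doublets kept and genes under the level of other nuclei left out. A value moved where it left the main interval, and turned where its sign was opposite to a main value whose interval left out 0. The cause of these shifts was not tested. The clustering without the mitochondrial filter also depended on numerical settings: an earlier run of the same steps with threads left free gave slightly other clusters there, with small shifts in its values and a few in or out of the main interval, while every other setting came out the same. The values given are from runs with a single thread, which repeated exactly. Of 63 share ratios, 41 moved and 4 turned with at most 1% mitochondrial UMIs, 30 and 4 without the mitochondrial filter, 27 and 2 with at least 1000 UMIs, and 3 and 1 with doublets kept. Of 384 list medians, 107 moved and 6 turned without the mitochondrial filter, and of 381, 73 and 6 with at least 1000 UMIs. Of 385, 88 moved and 7 turned with TMM factors, 68 and 11 with doublets kept, 65 and 0 with a mean over nuclei, and 38 and 2 at Leiden resolution 0.5. Of 640 gene ratios, 56 moved and 1 turned without the mitochondrial filter, 46 and 2 with TMM factors, and 41 and 4 with at least 1000 UMIs. Of 42 correlations, 35 moved and 1 turned with at least 500 UMIs per gene, 24 moved with genes under the level of other nuclei left out and 21 without the mitochondrial filter. TMM factors shift all genes of a class alike, so they leave a correlation as it is. The values that follow are those that turned, and those of the main results that moved. They are log2 ratios of shares or of genes, medians of log2 ratios over a list, or correlations across genes.

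Without the mitochondrial filter, the astrocyte share moved to -0.54 in TAFE4_oil/FE4, 0.31 in TAFE3_tam/TAFE3_oil, -1.07 in TAFE4_tam/TAFE4_oil and -1.28 in TAFE4_tam/TAFE3_tam. The microglia share moved to 0.28 in FE4/FE3, 1.85 in TAFE3_oil/FE3, 1.67 in TAFE4_oil/FE4, -0.051 in TAFE3_tam/TAFE3_oil and 0.15 in TAFE4_tam/TAFE3_tam, and disease-associated microglia genes in microglia moved to 0.37 in TAFE4_tam/TAFE4_oil. Interferon-response genes in microglia moved to 1.51 in TAFE3_oil/FE3 and 1.38 in TAFE4_tam/TAFE4_oil, and reactive astrocyte genes in astrocytes moved to 1.26 in TAFE3_oil/FE3, 1.86 in TAFE4_oil/FE4 and -0.081 in TAFE4_oil/TAFE3_oil. APOE in astrocytes moved to -1.76 in TAFE3_tam/TAFE3_oil and -1.93 in TAFE4_tam/TAFE4_oil, and the tau correlation moved to 0.654 in astrocytes, 0.382 in microglia, 0.291 in oligodendrocytes and 0.725 in excitatory neurons. The tamoxifen correlation moved to 0.142 in astrocytes, 0.090 in microglia and 0.217 in excitatory neurons. The inhibitory neuron share turned to 0.072 in FE4/FE3, the astrocyte share turned to -0.24 in FE4/FE3 and 0.099 in TAFE4_oil/TAFE3_oil, and the microglia share turned to -0.0022 in TAFE4_tam/TAFE4_oil. Heat shock and chaperone genes in astrocytes turned to 0.056 in TAFE4_tam/TAFE3_tam, and oxidative phosphorylation genes in microglia turned to -0.068 in TAFE3_oil/FE3. Ribosomal protein genes in astrocytes turned to -0.017 in TAFE3_tam/TAFE3_oil, ribosomal protein genes in microglia turned to -0.12 in TAFE3_oil/FE3, and neuronal transcripts in astrocytes turned to -0.078 in TAFE3_oil/FE3. Neuronal transcripts in microglia turned to -0.0077 in TAFE3_tam/TAFE3_oil, and Ap2s1 in astrocytes turned to 0.044 in TAFE3_oil/FE3.

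With doublets kept, disease-associated microglia genes in microglia moved to 1.88 in TAFE4_oil/FE4, 0.24 in TAFE4_tam/TAFE4_oil and 0.30 in TAFE4_tam/TAFE3_tam. Interferon-response genes in microglia moved to 1.35 in TAFE3_oil/FE3, 1.36 in TAFE4_oil/FE4, 1.36 in TAFE4_tam/TAFE4_oil and 0.95 in TAFE4_tam/TAFE3_tam, and reactive astrocyte genes in astrocytes moved to 1.87 in TAFE4_oil/FE4. APOE in astrocytes moved to -1.59 in TAFE4_tam/TAFE4_oil, and the tau correlation moved to 0.620 in astrocytes and 0.506 in microglia. The tamoxifen correlation moved to 0.110 in astrocytes and 0.126 in microglia. The CA1 pyramidal neuron share turned to 0.15 in TAFE4_tam/TAFE3_tam, and disease-associated microglia genes in microglia turned to 0.026 in TAFE4_oil/TAFE3_oil and 0.0011 in TAFE3_tam/TAFE3_oil. Lysosome and phagocytosis genes in microglia turned to 0.031 in TAFE4_oil/TAFE3_oil and 0.0072 in TAFE3_tam/TAFE3_oil, and complement genes in microglia turned to 0.017 in TAFE4_oil/TAFE3_oil. MHC class I genes in microglia turned to 0.0089 in TAFE4_oil/TAFE3_oil, homeostatic astrocyte genes in astrocytes turned to 0.18 in TAFE3_oil/FE3, and cholesterol synthesis genes in astrocytes turned to 0.027 in TAFE4_oil/FE4. Stress response genes in microglia turned to 0.27 in TAFE4_oil/FE4, neuronal transcripts in astrocytes turned to -0.48 in TAFE3_oil/FE3, and neuronal transcripts in microglia turned to -0.14 in TAFE4_oil/FE4. APOE in astrocytes turned to 0.061 in FE4/FE3, APOE in microglia turned to 0.022 in TAFE3_tam/TAFE3_oil, and the correlation of tau in APOE3 with tamoxifen in APOE4 turned to -0.012 in microglia.

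With at least 1000 UMIs per nucleus, the astrocyte share moved to 0.46 in FE4/FE3. The microglia share moved to 2.01 in TAFE3_oil/FE3, 2.88 in TAFE4_oil/FE4, 0.72 in TAFE4_oil/TAFE3_oil, -0.33 in TAFE3_tam/TAFE3_oil, 0.20 in TAFE4_tam/TAFE4_oil and 1.24 in TAFE4_tam/TAFE3_tam. Disease-associated microglia genes in microglia moved to 1.14 in TAFE3_oil/FE3, -0.0041 in TAFE4_oil/TAFE3_oil, 0.75 in TAFE4_tam/TAFE4_oil and 0.86 in TAFE4_tam/TAFE3_tam. Interferon-response genes in microglia moved to 1.34 in TAFE3_oil/FE3, 0.64 in TAFE4_oil/FE4, -0.23 in TAFE3_tam/TAFE3_oil, 1.85 in TAFE4_tam/TAFE4_oil and 1.58 in TAFE4_tam/TAFE3_tam. The oligodendrocyte share turned to 0.15 in TAFE4_oil/FE4, the microglia share turned to -0.15 in FE4/FE3, and MHC class II genes in microglia turned to -0.28 in TAFE4_oil/FE4. Stress response genes in microglia turned to 0.11 in TAFE4_oil/FE4, and oxidative phosphorylation genes in microglia turned to -0.00085 in TAFE3_oil/FE3 and 0.084 in TAFE4_tam/TAFE3_tam. Ribosomal protein genes in microglia turned to 0.073 in TAFE4_tam/TAFE3_tam, label check genes in microglia turned to 0.14 in TAFE4_tam/TAFE4_oil, and Rp9 in microglia turned to -0.43 in FE4/FE3. Cdh23 in microglia turned to 0.40 in TAFE4_oil/FE4, APOE in microglia turned to 0.15 in TAFE4_tam/TAFE4_oil, and Apoe in microglia turned to 0.16 in TAFE4_tam/TAFE4_oil.

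With the top expected share of doublets left out in every library, disease-associated microglia genes in microglia moved to 0.43 in FE4/FE3, 1.91 in TAFE3_oil/FE3, -0.051 in TAFE4_oil/TAFE3_oil, 0.39 in TAFE4_tam/TAFE4_oil and 0.37 in TAFE4_tam/TAFE3_tam. Interferon-response genes in microglia moved to 1.52 in TAFE3_oil/FE3, the tau correlation moved to 0.537 in astrocytes, and the tamoxifen correlation moved to 0.103 in microglia. The CA1 pyramidal neuron share turned to 0.14 in TAFE4_tam/TAFE3_tam, disease-associated microglia genes in microglia turned to 0.025 in TAFE3_tam/TAFE3_oil, and neuronal transcripts in astrocytes turned to -0.054 in TAFE3_oil/FE3. Neuronal transcripts in microglia turned to -0.068 in TAFE3_tam/TAFE3_oil, and APOE in astrocytes turned to 0.024 in FE4/FE3.

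With at most 1% mitochondrial UMIs, the astrocyte share moved to 2.44 in FE4/FE3, -2.55 in TAFE4_oil/FE4, -1.54 in TAFE4_oil/TAFE3_oil and -1.36 in TAFE3_tam/TAFE3_oil. The microglia share moved to 2.72 in FE4/FE3, 0.0034 in TAFE4_oil/FE4, 1.87 in TAFE4_tam/TAFE4_oil and 2.66 in TAFE4_tam/TAFE3_tam. The astrocyte share turned to 1.43 in TAFE3_oil/FE3, 0.98 in TAFE4_tam/TAFE4_oil and 0.81 in TAFE4_tam/TAFE3_tam, and the oligodendrocyte share turned to -1.37 in TAFE3_tam/TAFE3_oil.

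With a mean over nuclei of counts per 10000, disease-associated microglia genes in microglia moved to -0.063 in TAFE4_oil/TAFE3_oil, 0.19 in TAFE4_tam/TAFE4_oil and 0.16 in TAFE4_tam/TAFE3_tam. Interferon-response genes in microglia moved to 1.42 in TAFE4_oil/FE4, 1.33 in TAFE4_tam/TAFE4_oil and 0.81 in TAFE4_tam/TAFE3_tam, and reactive astrocyte genes in astrocytes moved to 1.25 in TAFE3_oil/FE3 and 0.049 in TAFE4_tam/TAFE4_oil. APOE in astrocytes moved to -1.68 in TAFE3_tam/TAFE3_oil and -1.99 in TAFE4_tam/TAFE4_oil. APOE in astrocytes turned to 0.092 in FE4/FE3, and APOE in microglia turned to 0.0083 in TAFE3_tam/TAFE3_oil.

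With TMM factors, disease-associated microglia genes in microglia moved to 1.17 in TAFE4_oil/FE4, and APOE in astrocytes moved to -1.75 in TAFE4_tam/TAFE4_oil. Synapse organisation and engulfment genes in astrocytes turned to -0.0092 in TAFE4_oil/TAFE3_oil, and presynaptic genes in inhibitory neurons turned to -0.0034 in TAFE4_oil/TAFE3_oil and 0.016 in TAFE4_tam/TAFE4_oil. Postsynaptic genes in inhibitory neurons turned to -0.082 in TAFE4_oil/FE4 and -0.017 in TAFE4_oil/TAFE3_oil, and stress response genes in oligodendrocytes turned to -0.10 in TAFE4_oil/FE4. Oxidative phosphorylation genes in excitatory neurons turned to -0.0015 in TAFE3_tam/TAFE3_oil, Mapt in excitatory neurons turned to 0.016 in FE4/FE3, and Prnp in excitatory neurons turned to -0.031 in TAFE4_oil/TAFE3_oil.

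With genes under the level of all other nuclei left out, the tau correlation moved to 0.543 in astrocytes, 0.377 in microglia and 0.790 in excitatory neurons, and the tamoxifen correlation moved to 0.065 in microglia and 0.397 in excitatory neurons. Postsynaptic genes in inhibitory neurons turned to 0.0063 in FE4/FE3 and -0.0058 in TAFE4_oil/FE4, and immediate early genes in inhibitory neurons turned to -0.10 in TAFE3_oil/FE3. Heat shock and chaperone genes in excitatory neurons turned to 0.11 in TAFE4_tam/TAFE4_oil, and p53 and DNA damage response genes in excitatory neurons turned to 0.072 in FE4/FE3.

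With at least 500 UMIs per gene, the tau correlation moved to 0.668 in astrocytes, 0.562 in microglia, 0.468 in oligodendrocytes and 0.760 in excitatory neurons. The tamoxifen correlation moved to 0.154 in astrocytes, -0.133 in microglia, -0.093 in oligodendrocytes and 0.315 in excitatory neurons. The tamoxifen correlation turned to -0.029 in dentate granule neurons.

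With list members of at least 100 UMIs, disease-associated microglia genes in microglia moved to 1.03 in TAFE4_oil/FE4 and -0.018 in TAFE3_tam/TAFE3_oil, and interferon-response genes in microglia moved to 2.02 in TAFE3_oil/FE3 and -0.25 in TAFE3_tam/TAFE3_oil. Reactive astrocyte genes in astrocytes moved to 1.35 in TAFE3_oil/FE3 and 1.18 in TAFE4_oil/FE4. Genes of the p53 response in astrocytes turned to -0.081 in TAFE3_oil/FE3.

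With no minimum beyond 1 UMI and a pseudocount of 1 UMI, disease-associated microglia genes in microglia moved to -0.16 in FE4/FE3, and reactive astrocyte genes in astrocytes moved to -0.29 in TAFE3_tam/TAFE3_oil.

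With Leiden resolution 0.5, label check genes in oligodendrocytes turned to -0.074 in TAFE3_oil/FE3 and 0.097 in TAFE3_tam/TAFE3_oil.

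With components centred per library, the CA1 pyramidal neuron share turned to 0.17 in TAFE4_tam/TAFE3_tam.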

Other observations

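Otulin, a deubiquitinase of linear ubiquitin chains, and Tnrc6c, of the microRNA silencing complex, were also read in each library. In granule neurons Otulin stood at 17.5 CPM in FE3, 13.1 in FE4, 39.3 in TAFE3_oil, 37.8 in TAFE3_tam and 28.1 in TAFE4_oil, and at 13.6 in TAFE4_tam. In CA1 neurons Tnrc6c stood at 337 CPM in FE3, 278 in FE4, 730 in TAFE3_oil, 899 in TAFE3_tam and 612 in TAFE4_oil, and at 453 in TAFE4_tam. Prnp in CA1 neurons stood at 221 and 161 CPM in FE3 and FE4 and between 341 and 374 in the TAFE libraries. Mouse Apoe was 10.4% of astrocyte Apoe and APOE UMIs in FE3 and 9.59% in TAFE4_tam.

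Interferon-response genes were spread unevenly over classes in TAFE4_tam. Summed CPM exceeded that of TAFE4_oil by 857 in oligodendrocyte precursors, 264 in CA1, 181 in CA2 or CA3, 130 in subicular or cortical and 90.7 in inhibitory neurons. These sums leave out cluster 20, of no named class and led by interferon genes, with 3262 CPM over 290 nuclei in TAFE4_tam and 2768 over 43 in TAFE4_oil, and the classes its nuclei came from were not settled. In TAFE3_tam against TAFE3_oil the sums differed by -60.6 in astrocytes, 2.15 in microglia and 16.8 in oligodendrocytes. APOE was also lower in endothelial nuclei with tamoxifen, at 1576 CPM in TAFE4_tam (72 nuclei) against 4684 in TAFE4_oil (104 nuclei). In TAFE3_tam it was 3469 CPM (99 nuclei) against 5942 in TAFE3_oil (127 nuclei). Granule neurons, read as background, had 862 against 1981 CPM with APOE4 and 811 against 1402 with APOE3. Loss in endothelial nuclei thus cannot be told apart from less free RNA. APOE in oligodendrocyte precursors was 4741 CPM in TAFE3_tam and 5139 in TAFE3_oil, and 5183 in TAFE4_tam and 6601 in TAFE4_oil.

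Whether deletion reached a part of the astrocytes or lowered APOE unevenly in all of them stays open. An even lowering would move medians and high values alike. Medians of APOE UMIs went from 13 to 2 with APOE3 and from 15 to 1 with APOE4. The 90th percentile went from 32 to 17.2 and from 34 to 14.2, which argued against an even lowering. At 1000 UMIs per nucleus 40.7% and 33.8% of astrocyte nuclei in TAFE3_tam and TAFE4_tam lay above the granule background, against 90.1% and 90.3% with oil. Those nuclei had medians of 46.7% and 43.8% of the oil value, which by the limit of 60% written beforehand argued against a rest of intact nuclei, while at a background shared by each pair, added afterwards, the values were 73.3% and 68.8%. Counts of unspliced and spliced APOE per nucleus, or reads over the floxed exons, could tell a mixture of intact and deleted astrocytes from a lower level in all of them.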
